A study of Rattus norvegicus with 50 samples.

How the data were processed

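RNA from 50 livers, 1 array per rat in 17 groups of 3 (2 for galactosamine at 48 h), was measured on Affymetrix rat arrays. The values deposited by the authors are log2 probe set signals on a common scale. RMA and limma were used per the submitters' processing notes, which give no version. All probe sets and 50 columns were read as deposited, with no further scaling and no filter on dim signals. Array medians lay between 4.954 and 5.093. The GAPDH 3′ minus 5′ difference, a sign of RNA degradation, lay between 0.0089 and 0.86. Groups were taken from the sample labels, since the design text of the series calls the group given both drugs the nevirapine group in 1 place. The labels used give no date, so batches could not be examined.

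Of 31099 probe sets, 20826 had 1 symbol and 436 had several, 9831 had no entry in the probe table (51 of them controls), and 6 controls with an entry were left out. For each gene the probe set with the highest mean was kept, which left 14217 genes, 4525 of them with more than 1 probe set.

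Limma 3.58.1 in R 4.3.3 fitted a mean for each of the 17 groups to all 50 arrays, so that the 22 comparisons shared 1 estimate of the spread per gene. Moderated statistics from eBayes were adjusted by the Benjamini-Hochberg method over the 14217 genes of a comparison, and genes with adjusted p under 0.05 were called. Rats were unpaired. Each treatment was compared with the vehicle group of the same time. Combination rats at 8 d had 15 d of dosing and were compared with vehicle at 15 d. The combination at 8 d was set against galactosamine as the difference of the effects on their own vehicle groups, and the interaction as the combination minus nevirapine at 15 d minus the galactosamine effect at 8 d. Times of nevirapine alone run from its first dose, so at 3 h to 48 h its dosing days differ from those of the combination. The vehicle group they share cannot match both.

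Before the data were examined, 28 gene lists, the comparisons, the tests and the rule for named genes were fixed. The rule takes the 8 largest rises and 8 largest falls among called genes whose groups do not overlap (without this condition for contrasts of 4 groups), leaving out symbols that start with LOC or RGD, and up to 4 members with the largest change from each list described. The text names the first of these in rank order. How many were named, and which lists were described in full (some with the smallest adjusted p and, mainly at 8 d, some others), was chosen afterwards. Of the other called lists, only those that kept their call in every setting but camera and without each rat are named. Also chosen afterwards was the level under which a change is given as a bound, the highest mean (4.37) of 27 control probe sets for Bacillus subtilis genes, whose means began at 1.94. Fry tested whether a list's genes moved, on balance, 1 way, which does not compare the list with other genes, and its p was adjusted over 616 tests, of which 188 were called. Camera with an estimated correlation kept 1 of these, the CAR and PXR list after 24 h of nevirapine. Unlike fry, it asks whether a list moved more than all other genes. A call lost with an estimated correlation can therefore reflect this other question, and not correlation alone.

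The scripts were tested on simulated data in which 100 genes were moved 1.5-fold and 100 moved 2-fold. Of those moved 2-fold, 91% were called in combination against control at 8 d, 93% in galactosamine against control at 48 h and 80% in the interaction. Of those moved 1.5-fold, 64%, 48% and 21% were called. Of 200 unmoved lists, 7 to 14 had an unadjusted fry p under 0.05.

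Alternatives were only the groups of a comparison in the fit, a prior with trend and robust estimation, the dimmest 40% of genes left out, the mean of all probe sets of a gene, cyclic loess normalization, array weights, all 15 vehicle rats as 1 control, vehicle at 8 d as control of the combination at 8 d, the treated groups at 8 d compared directly, camera, and each rat left out in turn. The GAPDH difference as a covariate, and 3 arrays that stood apart left out (rat63, rat70 and rat31), were added after seeing the data. Intervals of differences between list medians are 95% bootstrap intervals over genes with 10000 draws. Tables and plots used Numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9 under Python 3.11.15.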

Results

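RNA from the livers of 50 female Brown Norway rats was measured on rat expression arrays. Rats received galactosamine, nevirapine, both (the combination) or vehicle. Galactosamine is a sugar amine that harms hepatocytes by using up their uridine nucleotides, and nevirapine is an antiretroviral drug that can injure the liver. The study asked what happens in the liver over the 8 d after the combination, in which fibrosis occurred, and not after either drug alone. There were 17 groups. Time in the galactosamine and combination groups runs from the injection of 750 mg/kg, which combination rats received after 7 d of nevirapine. Nevirapine was given by mouth at 150, then 100, then 75 mg/kg. Livers were taken 2 h after the last oral dose, or 5 h after it in 3 h groups except nevirapine. That group was taken 3 h after it, unlike its vehicle rats. Comparisons with vehicle ask what each treatment changes, and the combination against either drug asks what the other drug adds. The number of arrays limits the precision. Limma tested 14217 genes. Genes said to have moved most were ranked among named genes whose rats did not overlap between groups. Values are log2 changes with the standard error of the fit (n = 3 per group, or 2 at 48 h of galactosamine), and rats carry their label names: rat1 to rat15 and rat99 to rat101 for vehicle, rat16 to rat27 and rat102 to rat104 for galactosamine, rat31 to rat45 for nevirapine and rat61 to rat87 for the combination. Where a group's mean was under log2 4.37, the highest of 27 probe sets for bacterial genes, its signal was not shown to exceed background. The change is then given as at least the brighter group's mean over this level, or without a size when both groups lie below it or 4 groups are contrasted.

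The mean correlation of an array with its group ranged from 0.979 (rat63, combination, 3 h) to 0.997, and no pair of arrays exceeded 0.9968.

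**Figure D1:**
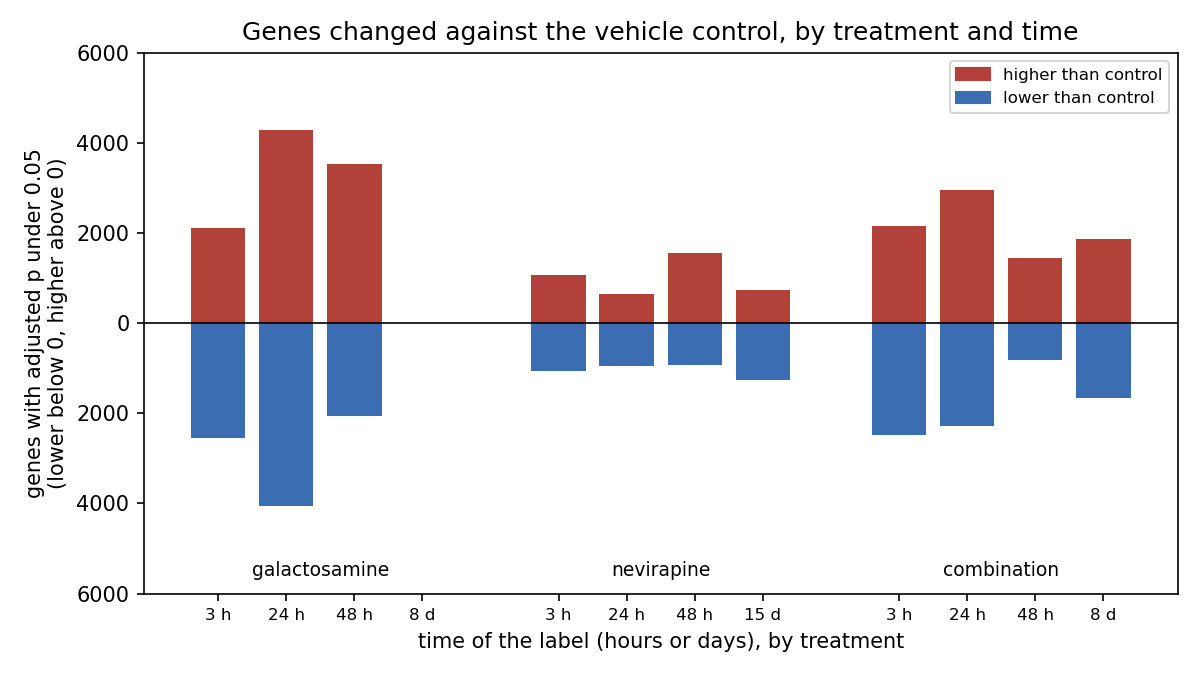
Number of genes with adjusted p under 0.05 in limma against the vehicle group of the same time, or of 15 d for combination rats at 8 d. Bars above 0 count higher genes and bars below 0 lower genes. Galactosamine bars add up to 8357 genes at 24 h and 5 at 8 d, while the combination has 3521 at 8 d.

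Within 3 h of galactosamine, livers had more transcript for the chemokines Xcl1 (at least 11.8-fold), Ccl2 (at least 5.53-fold) and Cxcl10 (log2 2.67 ± 0.52), which attract lymphocytes and monocytes. Cyp7a1 (log2 -3.89 ± 0.69), the entry enzyme of bile acid synthesis, and the hepatocyte transcription factor gene Cebpa (log2 -3.68 ± 0.18) fell most, and Exph5 (at least 4.76-fold lower) fell too. In all, 4680 genes changed, 2123 higher and 2557 lower. Of 18 endothelial genes, 13 rose and 5 did not pass (also adjusted over the list alone), with Ptprb (log2 1.11 ± 0.17) and Lyve1 (log2 1.05 ± 0.17). Fry called endothelial genes up (median 0.70, adjusted p = 1.41e-05, but adjusted p = 0.342 with an estimated correlation). Cytokine and chemokine genes moved up (median 0.76, adjusted p = 1.95e-05, but adjusted p = 0.342 with an estimated correlation). Of 26, 12 rose, 1 fell and 13 did not pass (14 rising and 1 falling adjusted over the list alone), with Ccl2, Ccl3 (log2 2.37 ± 0.32) and Ccl4 (log2 2.31 ± 0.27). The circadian clock list moved down (median -0.57, adjusted p = 3.26e-05, but adjusted p = 0.595 with an estimated correlation). In it, 4 rose, 8 fell and 4 did not pass (also adjusted over the list alone), led by Usp2 (log2 -1.97 ± 0.25) and Dbp (log2 -1.75 ± 0.42). Fry called 7 of 28 lists, and 6 kept the call in every setting but camera and without each rat. These included macrophage and monocyte, T and NK cell and interferon response genes upward (adjusted p = 0.000393 to 0.00902), against adjusted p = 0.537 to 0.698 with an estimated correlation.

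At 24 h the cell adhesion receptor Pvr (96.8-fold, log2 6.60 ± 0.42), the GTPase Rnd1 (77.4-fold, log2 6.27 ± 0.53), the TWEAK receptor Tnfrsf12a (log2 6.12 ± 0.32) and the stress transcription factor Atf3 (log2 5.85 ± 0.62) rose most. The bile acid enzymes Cyp8b1 (log2 -5.51 ± 0.55) and Cyp7a1 (log2 -4.78 ± 0.69) fell most, ahead of Vnn1 (log2 -4.75 ± 0.41), which makes pantothenate for coenzyme A. Here 8357 genes changed, 4299 higher and 4058 lower. For 18 bile acid genes, 16 fell and 2 did not pass (1 rising and 16 falling adjusted over the list alone), among them Cyp8b1, Cyp7a1, Nr0b2 (log2 -4.16 ± 0.35) and Slco1b2 (log2 -3.76 ± 0.27). As a group, bile acid genes moved down (median -2.00, adjusted p = 1.07e-17, but adjusted p = 0.0781 with an estimated correlation). Cdkn1a (log2 3.87 ± 0.33), Phlda3 (log2 3.65 ± 0.26) and Mdm2 (log2 3.17 ± 0.23) led the p53 target list, of which 13 rose and 2 fell (also adjusted over the list alone). As a list, p53 target genes moved up (median 1.41, adjusted p = 2.86e-16, but adjusted p = 0.161 with an estimated correlation). Of 23 ribosome biogenesis genes, 23 rose (also adjusted over the list alone), with Nop58 (log2 3.47 ± 0.20) and Rrs1 (log2 2.75 ± 0.24). Fry called ribosome biogenesis genes up (median 1.72, adjusted p = 6.71e-16, but adjusted p = 0.235 with an estimated correlation). Of 28 lists fry called 18, of which 14 kept the call in every setting but camera and without each rat. Further ones kept were interferon, NRF2, uridine and galactose, cytokine, ER stress and ATF4 and cell cycle genes upward (adjusted p = 1.86e-10 to 0.0144), and fatty acid oxidation, hepatocyte function, CAR and PXR, fatty acid synthesis and cholesterol biosynthesis genes downward (adjusted p = 5.28e-14 to 0.000785), against adjusted p = 0.235 to 0.971 with an estimated correlation. Of the lists described, Nolc1 (log2 2.65) and Sesn2 (log2 2.15) had a second probe set that changed the other way (log2 -0.41 and -1.11).

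The laminin gene Lama5 (33.2-fold, log2 5.05 ± 0.38), the NRF2 target Srxn1 (28.1-fold, log2 4.81 ± 0.47) and the tubulin Tubb6 (log2 4.53 ± 0.25) rose most at 48 h. Mmd2 (log2 -4.09 ± 0.33) fell most, and the methyltransferase Inmt (at least 18-fold lower) fell too. With 2 treated rats, 5600 genes changed, 3534 higher and 2066 lower (n = 2 against 3). p53 target genes moved up (median 0.80, adjusted p = 9.3e-11, but adjusted p = 0.192 with an estimated correlation). Of 15, 9 rose and 6 did not pass (10 rising adjusted over the list alone), with Phlda3 (log2 4.13 ± 0.30) and Cdkn1a (log2 2.80 ± 0.37). The uridine and galactose list moved up (median 0.63, adjusted p = 1.35e-09, but adjusted p = 0.235 with an estimated correlation). In it, 8 rose, 1 fell and 3 did not pass (also adjusted over the list alone), led by Ctps1 (log2 2.00 ± 0.28) and Cad (log2 1.75 ± 0.17). For 28 macrophage genes, 24 rose and 4 did not pass (also adjusted over the list alone), among them Gpnmb (log2 3.30 ± 0.39) and Lgals3 (log2 2.82 ± 0.39). As a group, macrophage genes moved up (median 1.60, adjusted p = 2.38e-06, but adjusted p = 0.449 with an estimated correlation). Called by fry were 12 of 28 lists, 6 of them in every setting but camera and without each rat. Kept calls include ribosome biogenesis, interferon, NRF2 and cell cycle genes upward (adjusted p = 1.41e-05 to 0.00208), against adjusted p = 0.595 to 0.843 with an estimated correlation. The GAPDH 3′ minus 5′ difference (RNA quality) averaged 0.138 in these rats and 0.613 in their controls, without overlap. The count became 3708 without rat27. The macrophage call ended with only these groups fitted (0.0737).

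At 8 d Zbtb17 (1.75-fold, log2 0.80 ± 0.15), which encodes a partner of MYC, rose, and Creld2 (2.3-fold lower, log2 -1.20 ± 0.22), an endoplasmic reticulum chaperone gene, Spetex2l1 (log2 -0.96 ± 0.19), Tbccd1 (log2 -0.88 ± 0.15) and Ccdc127 (log2 -0.55 ± 0.10) fell. These were the 5 of 14217 genes called by limma, 1 higher and 4 lower (n = 3 against 3), with 846 genes at an unadjusted p under 0.05. Creld2, Hyou1 (log2 -0.85 ± 0.22, adjusted p = 0.163) and Manf (log2 -0.84 ± 0.20, adjusted p = 0.125) led the ER stress list, of which 1 fell and 19 did not pass (7 falling adjusted over the list alone). As a list, ER stress genes moved down (median -0.28, adjusted p = 0.0031, but adjusted p = 0.0781 with an estimated correlation). Of 16 mast cell and eosinophil genes, 16 did not pass (2 rising adjusted over the list alone), with Mcpt1 (log2 1.14 ± 0.26, adjusted p = 0.0725) and Fcer1a (near background, adjusted p = 0.105). Fry called mast cell and eosinophil genes up (median 0.19, adjusted p = 0.0257, but adjusted p = 0.235 with an estimated correlation). The fibrillar collagen and matrix list was not called (median 0.16, adjusted p = 0.549), where 37 did not pass (none adjusted over the list alone), with Lox (near background in 1 group, adjusted p = 0.939) and Col1a1 (log2 0.64 ± 0.40, adjusted p = 0.915). Counts changed to 0 without rat100, rat103 or rat104 (561, 703 and 512 at unadjusted p under 0.05). They were 2 without rat101, 1 without rat99, 67 without rat102, 10 with only these groups fitted and 20 after cyclic loess. Array weights gave 293 and all vehicle rats as 1 control 718. Without 1 rat, adjusted p was above the threshold for the mast cell list (0.0548 to 0.143 without rat100, rat101 or rat103), Zbtb17 (0.098 to 0.463 without rat99, rat100, rat101, rat103 or rat104), Creld2 (0.0933 to 0.161 without rat99, rat100, rat103 or rat104), Spetex2l1 (0.0933 to 0.185 without rat99, rat100, rat101, rat103 or rat104), Tbccd1 (0.0933 to 0.161 without rat100, rat103 or rat104) and Ccdc127 (0.0933 to 0.161 without rat99, rat100, rat101, rat103 or rat104). The mast cell list call also ended with only these groups fitted (0.05) and without the dimmest 40% of genes (0.604), and the ER stress call with all vehicle rats as control (0.24). With all vehicle rats as 1 control, Creld2 was 0.06 and Spetex2l1 was 0.23. Higher genes made up 20% of those changed, or 70% after cyclic loess normalization.

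Within 3 h of the first dose of nevirapine, the Wnt and TGF-beta modulator Tsku (7.78-fold, log2 2.96 ± 0.30), Rell1 (6.88-fold, log2 2.78 ± 0.23) and the cytokine gene Gdf15 (log2 2.62 ± 0.40) rose most, and the transcription factor gene Atf3 (at least 7.88-fold) rose too. Falls included the small heat shock protein gene Hspb1 (log2 -1.41 ± 0.46) and Arhgef37 (at least 2-fold lower). Altogether 2142 genes changed, 1079 higher and 1063 lower. CAR and PXR genes moved up (median 0.23, adjusted p = 0.00116, but adjusted p = 0.289 with an estimated correlation). Of 23, 8 rose and 15 did not pass (also adjusted over the list alone), with Gadd45b (log2 2.11 ± 0.40), Abcb1a (log2 1.53 ± 0.18), Alas1 (log2 1.34 ± 0.23) and Ugt2b1 (log2 1.22 ± 0.20). The number became 1397 without rat1, 1313 without rat2, 1354 without rat32, 1279 with only these groups fitted and 3309 with array weights. Calls that 1 rat ended were Hspb1 (0.0618 to 0.16 without rat1, rat2, rat31 or rat33), by adjusted p.

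Tsku (8.91-fold, log2 3.16 ± 0.30), the methyltransferase Inmt (8.16-fold, log2 3.03 ± 0.54) and Tubb2a (log2 2.91 ± 0.37) rose most after 24 h of nevirapine. The clock output gene Dbp (log2 -3.37 ± 0.42) and the steroid dehydrogenase Hsd17b2 (log2 -2.57 ± 0.34) fell most, and the immediate early gene Fos (at least 6.19-fold lower) fell too. Limma called 1589 genes, 647 higher and 942 lower. The CAR and PXR list moved up (median 0.94, adjusted p = 5.85e-09, and adjusted p = 0.0259 with an estimated correlation). In it, 13 rose and 10 did not pass (17 rising and 1 falling adjusted over the list alone), led by Ces2c (log2 2.30 ± 0.25), Cyp3a2 (log2 2.14 ± 0.75, adjusted p = 0.0584), Ephx1 (log2 2.08 ± 0.23) and Abcc3 (log2 2.04 ± 0.27). For 18 NRF2 genes, 12 rose and 6 did not pass (also adjusted over the list alone), among them Me1 (log2 1.96 ± 0.29) and Srxn1 (log2 1.73 ± 0.42). As a group, NRF2 genes moved up (median 0.96, adjusted p = 9.65e-08, but adjusted p = 0.055 with an estimated correlation). Idi1 (log2 2.25 ± 0.47), Sqle (log2 2.21 ± 0.48) and Cyp51 (log2 2.13 ± 0.45) led the cholesterol biosynthesis list, of which 14 rose and 6 did not pass (16 rising adjusted over the list alone). As a list, cholesterol biosynthesis genes moved up (median 0.84, adjusted p = 0.00148, but adjusted p = 0.28 with an estimated correlation). In all 6 of 28 lists were called, and 3 kept the call in every setting but camera and without each rat. Called genes numbered 924 without rat4 and 2499 with array weights. By adjusted p, 1 rat ended the calls of Fos (0.0831 without rat6).

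The estrogen sulfotransferase Sult1e1 (13.1-fold, log2 3.72 ± 0.67), the cytochrome P450 Cyp3a2 (11.5-fold, log2 3.53 ± 0.75) and the carboxylesterase Ces2c (log2 3.01 ± 0.25) rose most after 48 h of nevirapine. The thyroxine carrier Serpina7 (log2 -2.40 ± 0.50) and the repressor Bcl6 (log2 -1.95 ± 0.48) fell most. There 2472 genes changed, 1557 higher and 915 lower. Of 23 CAR and PXR genes, 13 rose, 1 fell and 9 did not pass (13 rising and 2 falling adjusted over the list alone), with Cyp3a2, Ces2c and Akr7a3 (log2 1.80 ± 0.30). Fry called CAR and PXR genes up (median 0.69, adjusted p = 2.28e-06, but adjusted p = 0.192 with an estimated correlation). NRF2 genes moved up (median 0.59, adjusted p = 5.4e-05, but adjusted p = 0.235 with an estimated correlation). Of 18, 8 rose and 10 did not pass (13 rising and 1 falling adjusted over the list alone), with Me1 (log2 1.79 ± 0.29) and Srxn1 (log2 1.38 ± 0.42). Fry called 8 of 28 lists, and 3 kept the call in every setting but camera and without each rat. These included B and plasma cell genes downward (adjusted p = 0.00115), against adjusted p = 0.314 with an estimated correlation. The count became 1359 without rat12, 1534 without rat40, 4652 with array weights and 1396 with all vehicle rats as 1 control. Single rats ended the calls of Srxn1 (0.0505 to 0.0731 without rat10, rat12, rat41 or rat42), by adjusted p.

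After 15 d of nevirapine Sult1e1 (36.8-fold, log2 5.20 ± 0.67), Cyp3a2 (11.9-fold, log2 3.58 ± 0.75) and Ces2c (log2 3.31 ± 0.25) rose most, ahead of the semaphorin Sema3c (log2 2.65 ± 0.41). The nuclear receptor gene Nr4a1 (log2 -2.39 ± 0.64) and Noct (log2 -1.90 ± 0.49) fell most. In this group 1978 genes changed, 729 higher and 1249 lower. The CAR and PXR list moved up (median 0.58, adjusted p = 1.4e-06, but adjusted p = 0.0781 with an estimated correlation). In it, 12 rose, 1 fell and 10 did not pass (14 rising and 1 falling adjusted over the list alone), led by Cyp3a2, Ces2c, Ugt2b1 (log2 1.65 ± 0.20) and Abcc3 (log2 1.58 ± 0.27). For 21 fatty acid oxidation genes, 4 fell and 17 did not pass (7 falling adjusted over the list alone), among them Fgf21 (log2 -1.53 ± 0.36) and Hadha (log2 -1.0 ± 0.10). As a group, fatty acid oxidation genes moved down (median -0.41, adjusted p = 0.00437, but adjusted p = 0.595 with an estimated correlation). The matrix list was not called (median -0.11, adjusted p = 0.538), where 2 fell and 35 did not pass (also adjusted over the list alone), with Col6a2 (log2 -0.68 ± 0.35, adjusted p = 0.218) and Mfap4 (near background in 1 group, adjusted p = 0.428). Of 28 lists fry called 4, of which 3 kept the call in every setting but camera and without each rat. Further ones kept were T and NK cell genes downward (adjusted p = 0.00731), against adjusted p = 0.646 with an estimated correlation. The GAPDH difference averaged 0.202 in these rats and 0.0866 in their controls, without overlap. Counts changed to 1294 without rat13, 1316 without rat14, 1147 without rat44, 1253 without rat45, 4299 with only these groups fitted and 5018 with array weights. Without 1 rat, adjusted p was above the threshold for Nr4a1 (0.146 without rat13) and Noct (0.0761 without rat44).

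Rats given nevirapine for 7 d had, 3 h after galactosamine, high Sult1e1 (18.2-fold, log2 4.19 ± 0.67) and Cyp3a2 (log2 3.85 ± 0.75) together with the interferon-induced GTPase genes Gbp2 (at least 16.1-fold) and Gbp7 (at least 15.8-fold) and the injury marker Lcn2 (log2 4.11 ± 1.09). The thioesterase Acot1 (log2 -3.01 ± 0.97) and Rab30 (log2 -2.50 ± 0.41) fell most. Limma found 4627 changed genes, 2156 higher and 2471 lower. Gpnmb (log2 3.34 ± 0.35), Lgals3 (log2 3.07 ± 0.35) and Cd53 (log2 2.74 ± 0.28) led the macrophage list, of which 27 rose and 1 did not pass (also adjusted over the list alone). As a list, macrophage genes moved up (median 1.74, adjusted p = 1.61e-08, but adjusted p = 0.161 with an estimated correlation). Of 23 CAR and PXR genes, 10 rose, 1 fell and 12 did not pass (12 rising and 1 falling adjusted over the list alone), with Cyp3a2 and Ces2c (log2 2.77 ± 0.25). Fry called CAR and PXR genes up (median 0.57, adjusted p = 2.28e-06, but adjusted p = 0.235 with an estimated correlation). Interferon genes moved up (median 1.25, adjusted p = 2.28e-06, but adjusted p = 0.235 with an estimated correlation). Of 21, 13 rose and 8 did not pass (14 rising adjusted over the list alone), with Gbp2, Cxcl9 (log2 3.79 ± 0.34) and Cxcl10 (log2 2.87 ± 0.52). Called by fry were 15 of 28 lists, 6 of them in every setting but camera and without each rat. Kept calls include fatty acid oxidation, hepatocyte function and circadian clock genes downward (adjusted p = 4.85e-05 to 0.00304), against adjusted p = 0.449 to 0.758 with an estimated correlation. In rat63 the 606 genes that fell at least 2-fold after galactosamine had a median of -0.06, against -0.87 in rat61 and -1.09 in rat62. The number became 2138 with only these groups fitted. Calls that 1 rat ended were Acot1 (0.0659 without rat3), by adjusted p.

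Lcn2 (29.4-fold, log2 4.88 ± 1.09), Sult1e1 (27.1-fold, log2 4.76 ± 0.67) and the glutathione transferase Gstm3 (log2 4.60 ± 0.40) were the largest rises at 24 h. The serine dehydratase Sds (log2 -5.08 ± 0.69), Hsd17b2 (log2 -3.45 ± 0.34) and the histidine ammonia-lyase Hal (log2 -3.43 ± 0.37) fell most. At this time 5219 genes changed, 2948 higher and 2271 lower. The p53 target list moved up (median 0.81, adjusted p = 3.45e-11, but adjusted p = 0.148 with an estimated correlation). In it, 9 rose, 1 fell and 5 did not pass (11 rising and 1 falling adjusted over the list alone), led by Cdkn1a (log2 3.10 ± 0.33) and Phlda3 (log2 2.71 ± 0.26). For 23 ribosome biogenesis genes, 23 rose (also adjusted over the list alone), among them Nop58 (log2 2.52 ± 0.20) and Gar1 (log2 1.89 ± 0.21). As a group, ribosome biogenesis genes moved up (median 1.14, adjusted p = 3.45e-11, but adjusted p = 0.164 with an estimated correlation). In all 14 of 28 lists were called, and 12 kept the call in every setting but camera and without each rat. Others kept were interferon, NRF2, uridine and galactose, macrophage, CAR and PXR and cell cycle genes upward (adjusted p = 9.65e-08 to 0.005), and bile acid, hepatocyte function, fatty acid oxidation and fatty acid synthesis genes downward (adjusted p = 2.3e-08 to 1.73e-05), against adjusted p = 0.192 to 0.758 with an estimated correlation.

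Sult1e1 (54.5-fold, log2 5.77 ± 0.67), Cyp3a2 (14.7-fold, log2 3.88 ± 0.75) and Gstm3 (log2 3.27 ± 0.40) rose most at 48 h. The lipid phosphatase Mtmr7 (log2 -3.10 ± 0.51) and Mmd2 (log2 -2.70 ± 0.29) fell most. By 48 h 2265 genes changed, 1445 higher and 820 lower. Cyp3a2 and Ces2c (log2 2.78 ± 0.25) led the CAR and PXR list, of which 15 rose, 1 fell and 7 did not pass (15 rising and 2 falling adjusted over the list alone). As a list, CAR and PXR genes moved up (median 0.63, adjusted p = 1.14e-06, but adjusted p = 0.192 with an estimated correlation). Of 28 macrophage genes, 24 rose and 4 did not pass (25 rising adjusted over the list alone), with Gpnmb (log2 2.69 ± 0.35) and Lgals3 (log2 2.26 ± 0.35). Fry called macrophage genes up (median 1.22, adjusted p = 4.95e-06, but adjusted p = 0.192 with an estimated correlation). Fry called 11 of 28 lists, and 2 kept the call in every setting but camera and without each rat. These included NRF2 genes upward (adjusted p = 1.32e-05), against adjusted p = 0.235 with an estimated correlation. The GAPDH difference averaged 0.318 in these rats and 0.613 in their controls, without overlap. Called genes numbered 1402 without rat12, 1104 without rat70, 374 with only these groups fitted (198 higher and 176 lower) and 1478 without rat31, rat63 and rat70. The macrophage list call ended with only these groups fitted (0.0991).

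At 8 d periostin, Postn (at least 10.2-fold), a matrix protein gene, the macrophage elastase Mmp12 (at least 17.1-fold), asporin, Aspn (at least 10-fold), and lysyl oxidase, Lox (at least 6.71-fold), rose in the combination, as did Cyp3a2 (67.8-fold, log2 6.08 ± 0.75) and Sult1e1 (log2 5.62 ± 0.67). Fgf21 (5.18-fold lower, log2 -2.37 ± 0.36), the lipolysis inhibitor G0s2 (log2 -1.91 ± 0.29) and the activin gene Inhbe (log2 -1.84 ± 0.44) fell most. Against the 15 d vehicle rats 3521 genes changed, 1863 higher and 1658 lower (n = 3 against 3). Matrix genes moved up (median 1.09, adjusted p = 0.00317, but adjusted p = 0.595 with an estimated correlation). Of 37, 25 rose, 3 fell and 9 did not pass (27 rising and 3 falling adjusted over the list alone), with Postn, Lox, Col5a2 (log2 2.72 ± 0.42) and Lum (log2 2.65 ± 0.79). The TGF-beta and matrix turnover list moved up (median 0.19, adjusted p = 0.01, but adjusted p = 0.691 with an estimated correlation). In it, 11 rose, 2 fell and 16 did not pass (also adjusted over the list alone), with Mmp12, Ccn2 (log2 2.74 ± 0.41) and Inhbe. For 22 stellate cell and myofibroblast genes, 7 rose and 15 did not pass (also adjusted over the list alone), among them Vim (log2 1.51 ± 0.43), Pdgfra (log2 1.24 ± 0.20) and Cygb (log2 1.22 ± 0.23). As a group, stellate cell and myofibroblast genes moved up (median 0.22, adjusted p = 0.0249, but adjusted p = 0.714 with an estimated correlation). Gpnmb (log2 2.23 ± 0.35), Lgals3 (log2 1.44 ± 0.35) and Cybb (log2 1.31 ± 0.27) led the macrophage list, of which 9 rose and 19 did not pass (12 rising adjusted over the list alone). As a list, macrophage genes moved up (median 0.40, adjusted p = 0.0486, but adjusted p = 0.758 with an estimated correlation). Of 16 mast cell genes, 5 rose and 11 did not pass (5 rising and 1 falling adjusted over the list alone), with Mcpt10 (at least 1.89-fold), Cpa3 (at least 4.09-fold) and Mcpt1 (log2 2.31 ± 0.26). Fry called mast cell genes up (median 0.09, adjusted p = 1.73e-05, but adjusted p = 0.342 with an estimated correlation). Cell cycle genes moved up (median 1.07, adjusted p = 0.000386, but adjusted p = 0.379 with an estimated correlation). Of 35, 22 rose and 13 did not pass (26 rising adjusted over the list alone), with Cdkn3 (at least 3.93-fold), Ect2 (at least 3.99-fold) and Mki67 (at least 2.4-fold). Of 28 lists fry called 10, of which 5 kept the call in every setting but camera and without each rat. Further ones kept were CAR and PXR and NRF2 genes upward (adjusted p = 1.07e-07 to 0.0031), and fatty acid oxidation genes downward (adjusted p = 0.0015), against adjusted p = 0.161 to 0.553 with an estimated correlation. Against the 8 d vehicle rats 34 of the called named genes lost their call. The count became 5557 with array weights and 1763 against 8 d vehicle (1126 higher and 637 lower). By adjusted p, 1 rat ended the calls of the macrophage list (0.051 to 0.199 without rat13, rat14, rat15, rat73 or rat87), the stellate cell list (0.0622 to 0.0763 without rat15 or rat87), Lum (0.0578 to 0.0585 without rat15 or rat87) and Inhbe (0.0536 without rat84). The macrophage list call ended with only these groups fitted (0.105), without the dimmest 40% of genes (0.0837) and after cyclic loess (0.0582). It also ended against 8 d vehicle (0.122) and with the GAPDH covariate (0.0547). The stellate cell call ended with the mean of probe sets (0.0823) and against 8 d vehicle (0.0509), and the cell cycle call with only these groups fitted (0.102). With the dimmest 40% of genes left out, the mast cell list turned the other way (adjusted p = 0.0856).

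**Figure D2:**
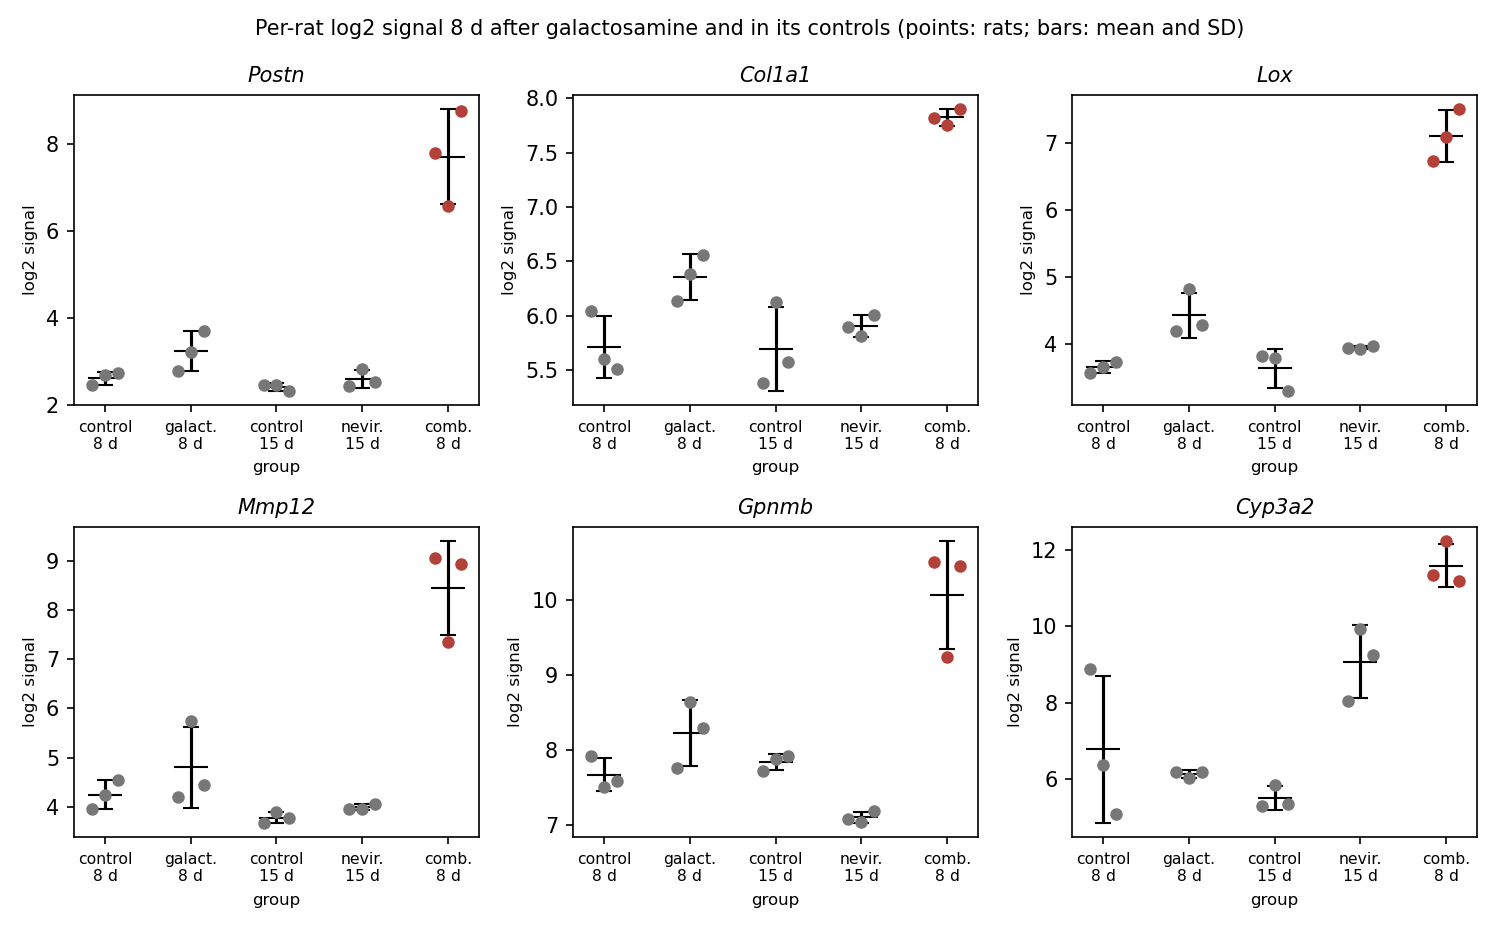
Log2 signal of 6 genes in single rats (points) with the mean and SD (bars) in the groups taken 8 d after galactosamine and in the 8 d and 15 d vehicle and 15 d nevirapine groups. The 3 combination rats lie above every other rat plotted for Postn, Lox and Mmp12.

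These rats differed by 7 d of nevirapine before the same galactosamine dose. At 3 h Sult1e1 (22.2-fold, log2 4.47 ± 0.67), Lcn2 (16.1-fold, log2 4.01 ± 1.09), Cyp3a2 (log2 3.49 ± 0.75), Cyp7a1 (log2 3.40 ± 0.69) and Postn (at least 2.84-fold) were higher in the combination. The chemokine gene Xcl1 (log2 -3.32 ± 0.18), Acot1 (log2 -3.06 ± 0.97) and the sterol transporter Abcg5 (log2 -2.04 ± 0.37) were lower. Here 2518 genes changed, 1514 higher and 1004 lower. The CAR and PXR list moved up (median 0.33, adjusted p = 6.21e-05, but adjusted p = 0.28 with an estimated correlation). In it, 9 were higher, 1 lower and 13 did not pass (11 higher and 1 lower adjusted over the list alone), led by Cyp3a2 and Ces2c (log2 2.21 ± 0.25). For 21 fatty acid oxidation genes, 12 were lower and 9 did not pass (13 lower adjusted over the list alone), among them Acot1 and Fgf21 (log2 -1.65 ± 0.36). As a group, fatty acid oxidation genes moved down (median -0.43, adjusted p = 0.000571, but adjusted p = 0.336 with an estimated correlation). Called by fry were 9 of 28 lists, 3 of them in every setting but camera and without each rat. Kept calls include macrophage genes upward (adjusted p = 0.00185), against adjusted p = 0.444 with an estimated correlation. Counts changed to 1602 without rat63 and 757 with only these groups fitted (573 higher and 184 lower). Single rats ended the calls of Acot1 (0.0535 to 0.0965 without rat16, rat18, rat61 or rat63) and Postn (0.0502 without rat63), by adjusted p. Higher genes made up 60.1% of those changed, or 71.2% after cyclic loess normalization.

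Sult1e1 (at least 146-fold) and Cyp7a1 (45.3-fold, log2 5.50 ± 0.69) were higher with the combination at 24 h than with galactosamine alone, as was the vasopressin receptor Avpr1a (log2 3.77 ± 0.26). Rnd1 (log2 -4.26 ± 0.53), Atf3 (log2 -4.21 ± 0.62) and Pvr (log2 -3.50 ± 0.42) were lower. Between these groups 5371 genes changed, 2298 higher and 3073 lower. Aldh1a1 (log2 3.76 ± 0.29) and Cyp3a2 (at least 10.1-fold) belong to the CAR and PXR list, of which 15 were higher and 8 did not pass (17 higher adjusted over the list alone). As a list, CAR and PXR genes moved up (median 1.04, adjusted p = 1.16e-11, but adjusted p = 0.117 with an estimated correlation). Of 18 bile acid genes, 13 were higher, 1 lower and 4 did not pass (also adjusted over the list alone), with Cyp7a1 and Nr0b2 (log2 2.80 ± 0.35). Fry called bile acid genes up (median 1.31, adjusted p = 2.42e-11, but adjusted p = 0.109 with an estimated correlation). Immediate early genes moved down (median -1.89, adjusted p = 2.28e-06, but adjusted p = 0.371 with an estimated correlation). Of 16, 11 were lower and 5 did not pass (also adjusted over the list alone), with Junb (log2 -2.95 ± 0.35) and Fosl1 (log2 -2.57 ± 0.36). In all 12 of 28 lists were called, and 5 kept the call in every setting but camera and without each rat. Others kept were erythroid genes upward (adjusted p = 2.37e-05), and p53 target and ribosome biogenesis genes downward (adjusted p = 2.28e-06 to 1.31e-05), against adjusted p = 0.406 to 0.501 with an estimated correlation. The GAPDH difference averaged 0.235 with the combination and 0.457 with galactosamine, without overlap. The number became 2739 with only these groups fitted. The immediate early call ended with only these groups fitted (0.102).

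At 48 h Sult1e1 (73.9-fold, log2 6.21 ± 0.75), Inmt (at least 32.4-fold) and Cyp3a2 (log2 4.28 ± 0.84) were higher with the combination. The laminin gene Lama5 (log2 -4.98 ± 0.38) and Wnt4 (log2 -4.54 ± 0.51) were lower than with galactosamine alone. Between these rats 4163 genes changed, 1726 higher and 2437 lower. The CAR and PXR list moved up (median 1.27, adjusted p = 7.94e-11, but adjusted p = 0.0692 with an estimated correlation). In it, 17 were higher and 6 did not pass (also adjusted over the list alone), led by Cyp3a2, Cyp3a9 (log2 2.90 ± 0.34) and Ugt2b1 (log2 2.64 ± 0.23). For 15 p53 target genes, 1 was higher, 9 lower and 5 did not pass (2 higher and 9 lower adjusted over the list alone), among them Phlda3 (log2 -3.0 ± 0.30), Aen (log2 -2.37 ± 0.22) and Sesn2 (log2 -1.96 ± 0.22). As a group, p53 target genes moved down (median -0.81, adjusted p = 7.14e-08, but adjusted p = 0.235 with an estimated correlation). Fry called 4 of 28 lists, and 1 kept the call in every setting but camera and without each rat. The GAPDH difference averaged 0.318 with the combination and 0.138 with galactosamine, without overlap. Called genes numbered 2590 without rat26, 2407 without rat27 and 1772 with only these groups fitted. The p53 target call ended with only these groups fitted (0.07).

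Each arm was here taken against its own vehicle rats. Relative to galactosamine alone, the combination had higher Cyp3a2 (106-fold, log2 6.73 ± 1.06) and Sult1e1 (log2 4.38 ± 0.95), and higher Postn (adjusted p = 0.00509) and Mmp12 (adjusted p = 8.95e-05). Fgf21 (6.68-fold lower, log2 -2.74 ± 0.51) and Prr15 (log2 -2.20 ± 0.70) were lower. By this measure 1594 genes changed, 835 higher and 759 lower. Cyp3a2 and Ces2c (log2 3.84 ± 0.36) led the CAR and PXR list, of which 8 were higher and 15 did not pass (11 higher adjusted over the list alone). As a list, CAR and PXR genes moved up (median 0.66, adjusted p = 1.38e-05, but adjusted p = 0.161 with an estimated correlation). Of 21 fatty acid oxidation genes, 7 were lower and 14 did not pass (9 lower adjusted over the list alone), with Fgf21 and Acot1 (log2 -1.54 ± 1.37, adjusted p = 0.505). Fry called fatty acid oxidation genes down (median -0.57, adjusted p = 0.00619, but adjusted p = 0.443 with an estimated correlation). Cell cycle genes moved up (median 0.86, adjusted p = 0.0388, but adjusted p = 0.595 with an estimated correlation). Of 35, 14 were higher and 21 did not pass (19 higher adjusted over the list alone), with Ect2 (adjusted p = 0.00351) and Cdkn3 (adjusted p = 0.0262). The matrix list was not called (median 0.86, adjusted p = 0.126), where 7 were higher, 3 lower and 27 did not pass (19 higher and 3 lower adjusted over the list alone), with Postn, Lox (adjusted p = 0.0146) and Lum (log2 2.57 ± 1.11, adjusted p = 0.127). The macrophage list was not called (median 0.36, adjusted p = 0.242), where 3 were higher and 25 did not pass (also adjusted over the list alone), with Gpnmb (log2 1.67 ± 0.50) and Cybb (log2 1.27 ± 0.39). Of 28 lists fry called 4, of which 2 kept the call in every setting but camera and without each rat. The count became 931 without rat100, 1017 without rat87, 3125 with only these groups fitted and 3956 with array weights. Without 1 rat, adjusted p was above the threshold for the cell cycle list (0.0503 to 0.171 without rat13, rat14, rat15, rat87, rat100, rat101, rat103 or rat104), Prr15 (0.0578 to 0.109 without rat13, rat14, rat73, rat87, rat99, rat100 or rat102), Cdkn3 (0.056 to 0.132 without rat13, rat87, rat100 or rat103), Gpnmb (0.0562 to 0.081 without rat13, rat73, rat87, rat100 or rat102) and Cybb (0.05 to 0.104 without rat13, rat14, rat73, rat87, rat100 or rat102). The cell cycle list call also ended with only these groups fitted (0.117) and without the dimmest 40% of genes (0.632).

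At 3 h nevirapine rats had received 1 dose and combination rats 7 d of dosing. The neutrophil chemokine Cxcl1 (12.9-fold, log2 3.69 ± 0.80), Gbp2 (12.5-fold, log2 3.64 ± 0.43) and Cxcl10 (at least 10.5-fold) were higher in the combination. Acot1 (log2 -2.72 ± 0.97) and Abcg5 (log2 -2.65 ± 0.37) were lower. In this contrast 3239 genes changed, 1570 higher and 1669 lower. The T and NK cell list moved up (median 0.38, adjusted p = 1.43e-06, but adjusted p = 0.192 with an estimated correlation). In it, 9 were higher and 13 did not pass (13 higher adjusted over the list alone), with Gzma (at least 5.69-fold) and Gzmb (at least 1.68-fold). For 28 macrophage genes, 25 were higher and 3 did not pass (26 higher adjusted over the list alone), among them Gpnmb (log2 2.54 ± 0.35) and Lgals3 (log2 2.34 ± 0.35). As a group, macrophage genes moved up (median 1.18, adjusted p = 6.7e-06, but adjusted p = 0.235 with an estimated correlation). Called by fry were 13 of 28 lists, 5 of them in every setting but camera and without each rat. Kept calls include interferon, neutrophil and fatty acid synthesis genes upward (adjusted p = 1.06e-05 to 0.00142), and fatty acid oxidation genes downward (adjusted p = 0.00202), against adjusted p = 0.235 to 0.497 with an estimated correlation. Counts changed to 1588 without rat62 and 371 with only these groups fitted (313 higher and 58 lower). Calls that 1 rat ended were Acot1 (0.0588 to 0.225 without rat31, rat32, rat61, rat62 or rat63), by adjusted p. The T and NK cell call ended without the dimmest 40% of genes (0.279).

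Lcn2 (18.6-fold, log2 4.22 ± 1.09), Gbp2 (at least 8.75-fold) and the antigen presentation genes RT1-Da (log2 3.96 ± 0.26) and Cd74 (log2 3.63 ± 0.25) were higher with the combination at 24 h. Inmt (log2 -4.38 ± 0.54), A1bg (log2 -3.44 ± 1.18) and the desaturase Fads1 (log2 -3.19 ± 0.32) were lower. Nevirapine rats had then had 2 doses and combination rats 8 d of dosing. Across the arrays 5032 genes changed, 2980 higher and 2052 lower. Phlda3 (log2 3.39 ± 0.26) and Ccng1 (log2 2.85 ± 0.17) led the p53 target list, of which 9 were higher and 6 did not pass (also adjusted over the list alone). As a list, p53 target genes moved up (median 0.67, adjusted p = 1.26e-10, but adjusted p = 0.176 with an estimated correlation). Of 18 bile acid genes, 1 was higher, 15 lower and 2 did not pass (also adjusted over the list alone), with Abcg5 (log2 -3.02 ± 0.37) and Cyp7a1 (log2 2.64 ± 0.69). Fry called bile acid genes down (median -0.71, adjusted p = 1.25e-09, but adjusted p = 0.133 with an estimated correlation). In all 14 of 28 lists were called, and 12 kept the call in every setting but camera and without each rat. Others kept were macrophage, ribosome biogenesis, interferon, uridine and galactose, T and NK cell and cell cycle genes upward (adjusted p = 6.91e-09 to 0.00417), and fatty acid synthesis, cholesterol biosynthesis, hepatocyte function and CAR and PXR genes downward (adjusted p = 1.14e-06 to 0.00185), against adjusted p = 0.235 to 0.753 with an estimated correlation. By adjusted p, 1 rat ended the calls of A1bg (0.0946 to 0.121 without rat38 or rat79).

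At 48 h the class II antigen presentation genes Cd74 (14.4-fold, log2 3.84 ± 0.25), RT1-Db1 (12.3-fold, log2 3.62 ± 0.26) and RT1-Da (log2 3.55 ± 0.26) were higher. Mtmr7 (log2 -2.51 ± 0.51) and Mmd2 (log2 -2.17 ± 0.29) were lower than after nevirapine, of which these rats had had 3 doses against 9 d in the combination. With this difference in dosing 2472 genes changed, 1387 higher and 1085 lower. Macrophage genes moved up (median 1.51, adjusted p = 2.32e-07, but adjusted p = 0.148 with an estimated correlation). Of 28, 25 were higher and 3 did not pass (26 higher adjusted over the list alone), with Gpnmb (log2 2.64 ± 0.35) and Cd5l (log2 2.15 ± 0.30). The interferon list moved up (median 1.25, adjusted p = 1.69e-05, but adjusted p = 0.235 with an estimated correlation). In it, 17 were higher and 4 did not pass (also adjusted over the list alone), with Gbp2 (at least 5.58-fold) and Cxcl9 (log2 2.16 ± 0.34). For 23 acute phase response genes, 5 were higher, 1 lower and 17 did not pass (6 higher and 1 lower adjusted over the list alone), among them Lcn2 (log2 3.61 ± 1.09) and A2m (near background in 1 group, adjusted p = 0.209). As a group, acute phase response genes moved up (median 0.25, adjusted p = 0.0346, but adjusted p = 0.778 with an estimated correlation). Fry called 10 of 28 lists, and 2 kept the call in every setting but camera and without each rat. These included B cell genes upward (adjusted p = 0.000243), against adjusted p = 0.369 with an estimated correlation. The number became 1374 without rat40 and 533 with only these groups fitted (271 higher and 262 lower). Single rats ended the calls of the acute phase list (0.052 to 0.221 without rat40, rat41, rat42, rat71 or rat72) and Lcn2 (0.0528 to 0.179 without rat41, rat42, rat71 or rat72), by adjusted p. List calls also ended with only these groups fitted for acute phase (0.264) and interferon (0.0903) genes and after cyclic loess for acute phase (0.0947) genes.

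Both groups had 15 d of nevirapine, so that they differed by galactosamine. Postn (at least 10.2-fold), Mmp12 (at least 17.1-fold), Aspn (9.98-fold, log2 3.32 ± 0.55), Lox (at least 6.71-fold) and the collagen Col6a5 (8.92-fold, log2 3.16 ± 0.45) were higher in the combination. The macrophage gene Gpnmb (log2 2.96 ± 0.35) and the mast cell protease gene Mcpt10 (at least 1.89-fold) were higher too. A1bg (16.4-fold lower, log2 -4.04 ± 1.18), the endothelial gene Esm1 (at least 1.61-fold lower) and the reductase Akr1b7 (log2 -1.88 ± 0.42) were lower. Limma called 1763 genes, 1323 of them higher and 440 lower (n = 3 against 3). Postn, Lox, Mfap4 (at least 6.55-fold) and Col5a2 (log2 2.42 ± 0.42) belong to the matrix list, of which 23 were higher and 14 did not pass (29 higher and 2 lower adjusted over the list alone). As a list, matrix genes moved up (median 1.08, adjusted p = 0.00024, but adjusted p = 0.314 with an estimated correlation). Of 29 TGF-beta genes, 11 were higher and 18 did not pass (14 higher and 2 lower adjusted over the list alone), with Mmp12, Mmp2 (log2 2.17 ± 0.35) and Ccn2 (log2 1.98 ± 0.41). Fry called TGF-beta genes up (median 0.32, adjusted p = 0.000238, but adjusted p = 0.371 with an estimated correlation). Macrophage genes moved up (median 0.94, adjusted p = 9.67e-05, but adjusted p = 0.241 with an estimated correlation). Of 28, 23 were higher and 5 did not pass (24 higher adjusted over the list alone), with Gpnmb, Lgals3 (log2 2.02 ± 0.35) and Cybb (log2 1.70 ± 0.27). The mast cell list moved up (median 0.19, adjusted p = 2.91e-06, but adjusted p = 0.235 with an estimated correlation). In it, 5 were higher and 11 did not pass (also adjusted over the list alone), with Mcpt10, Mcpt1 (log2 2.10 ± 0.26) and Ccl11 (at least 1.45-fold). For 35 cell cycle genes, 17 were higher and 18 did not pass (21 higher adjusted over the list alone), among them Ect2 (at least 3.99-fold) and Cdkn3 (at least 3.93-fold). As a group, cell cycle genes moved up (median 0.87, adjusted p = 0.0031, but adjusted p = 0.475 with an estimated correlation). Pdgfrb (log2 1.88 ± 0.25), Cygb (log2 1.57 ± 0.23) and Vim (log2 1.31 ± 0.43) led the stellate cell list, of which 6 were higher and 16 did not pass (also adjusted over the list alone). As a list, stellate cell genes moved up (median 0.32, adjusted p = 0.014, but adjusted p = 0.701 with an estimated correlation). Of 18 endothelial genes, 7 were higher and 11 did not pass (10 higher adjusted over the list alone), with Vwf (log2 1.14 ± 0.21) and Tie1 (log2 0.88 ± 0.16). Fry called endothelial genes up (median 0.39, adjusted p = 0.00286, but adjusted p = 0.504 with an estimated correlation). Cholangiocyte and progenitor genes moved up (median 0.43, adjusted p = 0.0223, but adjusted p = 0.743 with an estimated correlation). Of 17, 5 were higher, 1 lower and 11 did not pass (also adjusted over the list alone), with Cd24 (log2 1.29 ± 0.27) and Gpc3 (at least 1.66-fold). Of 28 lists fry called 8, of which 5 kept the call in every setting but camera and without each rat. Called genes numbered 1023 without rat87, 1070 without the dimmest 40% of genes and 3547 with array weights. Without 1 rat, adjusted p was above the threshold for the cholangiocyte list (0.0508 to 0.0678 without rat44, rat73 or rat87), the cell cycle list (0.0664 without rat87), A1bg (0.0521 to 0.0791 without rat43, rat45 or rat73), Vim (0.0758 to 0.156 without rat43, rat44, rat45, rat73 or rat87), Gpc3 (0.084 without rat84), Cdkn3 (0.0911 without rat87) and Ccl11 (0.0982 without rat87). Further list calls ended with only these groups fitted for cell cycle (0.15) genes and without the dimmest 40% of genes for mast cell (0.525) genes.

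The interaction asks where both drugs together depart from the sum of their log2 effects. Postn (adjusted p = 0.0201), Mmp12 (adjusted p = 0.000838), Cyp7a1 (log2 3.75 ± 0.98) and the secreted lipocalin gene Pbsn (adjusted p = 0.0205) exceeded the sum. Cux2 (3.81-fold lower, log2 -1.93 ± 0.50) fell short of it. Of 14217 genes, 401 had an interaction, 291 above the sum and 110 below it. The macrophage list moved up (median 0.88, adjusted p = 0.00815, but adjusted p = 0.338 with an estimated correlation). In it, 5 lay above the sum and 23 did not pass (22 above adjusted over the list alone), led by Gpnmb (log2 2.40 ± 0.50) and Lgals3 (log2 1.79 ± 0.50). For 29 TGF-beta genes, 5 lay above the sum and 24 did not pass (11 above and 1 below adjusted over the list alone), among them Mmp12 and Ccn2 (log2 2.15 ± 0.58). As a group, TGF-beta genes moved up (median 0.24, adjusted p = 0.0309, but adjusted p = 0.595 with an estimated correlation). Postn, Lox (adjusted p = 0.0654) and Mfap4 (adjusted p = 0.0405) belong to the matrix list, of which 7 lay above the sum and 30 did not pass (18 above and 1 below adjusted over the list alone). As a list, matrix genes moved up (median 0.92, adjusted p = 0.0355, but adjusted p = 0.577 with an estimated correlation). Called by fry were 5 of 28 lists, 1 of them in every setting but camera and without each rat. The count became 107 without rat100, 221 without rat102, 214 without rat104, 233 without rat43, 195 without rat44, 234 without rat45, 114 without rat87, 1340 with only these groups fitted, 215 without the dimmest 40% of genes and 2076 with array weights. Calls that 1 rat ended were the matrix list (0.0587 to 0.0802 without rat44, rat87, rat100, rat102 or rat104), the TGF-beta list (0.0502 to 0.0664 without rat43, rat44, rat87, rat100, rat102 or rat104), Postn (0.0524 to 0.0865 without rat87, rat100 or rat102), Cyp7a1 (0.0613 to 0.101 without rat43, rat45, rat84, rat87, rat99, rat100 or rat102), Pbsn (0.0593 to 0.106 without rat84, rat87, rat100 or rat104), Cux2 (0.054 to 0.0897 without rat43, rat45, rat84, rat87, rat100, rat103 or rat104), Mfap4 (0.0583 to 0.117 without rat43, rat44, rat84, rat87, rat99, rat100, rat102, rat103 or rat104), Ccn2 (0.0511 to 0.0885 without rat43, rat44, rat45, rat84, rat87, rat99, rat100, rat103 or rat104) and Lgals3 (0.0508 to 0.124 without rat43, rat44, rat45, rat73, rat87, rat99, rat100, rat101, rat102 or rat104), by adjusted p. The TGF-beta list call ended with the mean of probe sets (0.0597).

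As background, vehicle rats of 15 d and 8 d were compared. The nuclear receptor gene Nr4a1 (4.92-fold, log2 2.30 ± 0.64), Slc25a25 (log2 1.72 ± 0.41) and the kinase Sik1 (log2 1.41 ± 0.28) were higher at 15 d. Arrdc3 (4.62-fold lower, log2 -2.21 ± 0.43), the zinc transporter Slc30a1 (at least 1.87-fold lower) and Mug1 (log2 -1.53 ± 0.37) were lower. Between vehicle groups 473 genes changed, 236 higher and 237 lower (n = 3 against 3). Of 20 ER stress genes, 3 were lower and 17 did not pass (1 higher and 5 lower adjusted over the list alone), with Chac1 (log2 1.36 ± 0.44, adjusted p = 0.0781), Creld2 (log2 -1.04 ± 0.22) and Sdf2l1 (log2 -0.69 ± 0.21, adjusted p = 0.0654). Fry called ER stress genes down (median -0.29, adjusted p = 0.0223, but adjusted p = 0.327 with an estimated correlation). The matrix list was not called (median 0.05, adjusted p = 0.753), where 1 was higher and 36 did not pass (2 higher adjusted over the list alone), with Lum (log2 -1.13 ± 0.79, adjusted p = 0.511) and Col5a2 (log2 -0.48 ± 0.42, adjusted p = 0.632). Counts changed to 135 without rat100, 235 without rat101, 218 without rat99, 181 without rat13, 154 without rat14, 188 without rat15, 1404 with only these groups fitted and 2379 with array weights. By adjusted p, 1 rat ended the calls of the ER stress list (0.0522 to 0.0743 without rat14, rat15 or rat100), Nr4a1 (0.0635 to 0.327 without rat13, rat14, rat99, rat100 or rat101), Slc25a25 (0.0541 to 0.0752 without rat13, rat15, rat100 or rat101), Mug1 (0.0806 to 0.115 without rat14 or rat100) and Creld2 (0.0597 without rat100).

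**Figure D3:**
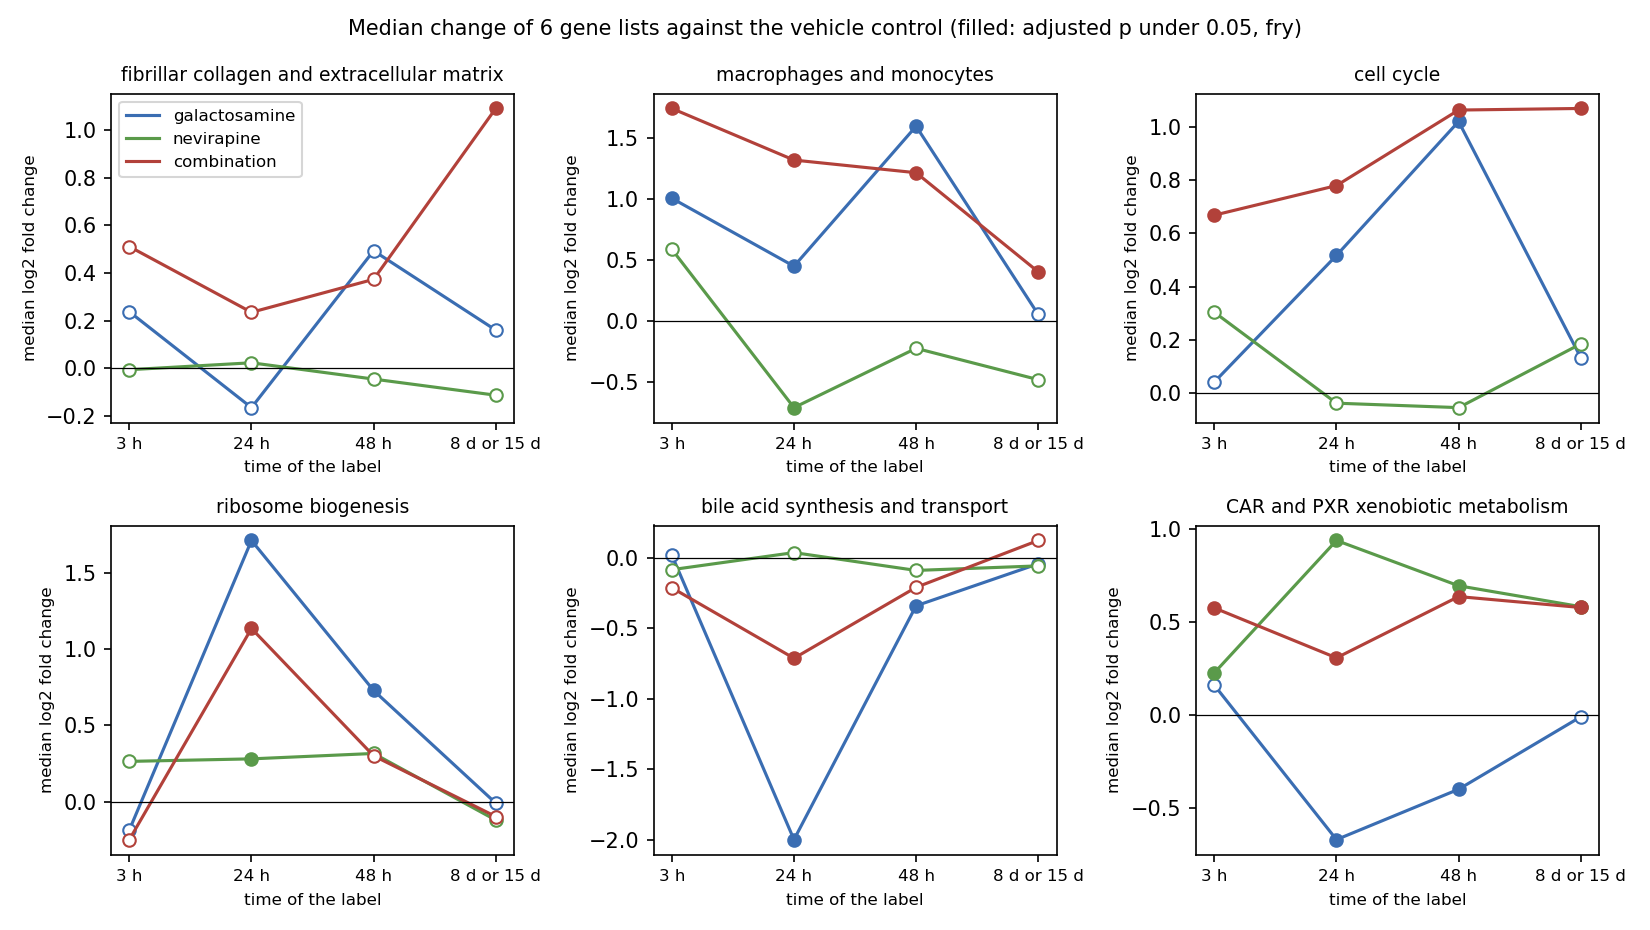
Median log2 change of 6 gene lists against the vehicle group at each time, for galactosamine (blue), nevirapine (green) and the combination (red). Filled points have adjusted p under 0.05 by fry. The matrix median for the combination at 8 d is 1.09.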

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

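Chosen only after the results were seen were the tests of hepatocyte share, of RNA quality at 8 d (where this one replaced 2 earlier forms that had little chance to fail) and in rat63 (whose range was narrowed afterwards), and of a swapped sample.

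Effects differed between times when the difference itself was tested in limma. For galactosamine, 7384 genes differed between 24 h and 3 h, 5179 between 48 h and 24 h, and 3395 between 8 d and 48 h. For nevirapine the numbers were 1286, 1415 and, for 15 d against 48 h, 1018. For the combination they were 4074, 2080 and 1281. Outside the genes compared, 835 of 10216 probe sets with no single gene symbol changed in combination against nevirapine at 8 d, while 232 differed between vehicle groups of 15 d and 8 d.

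Matrix and macrophage genes were higher in the combination than after nevirapine at 8 d, with list medians of 1.08 and 0.943, but adjusted p = 0.314 and 0.241 with an estimated correlation, and 14 of 37 and 5 of 28 genes not passing. A lower share of hepatocytes would raise markers of all other cells alike. The macrophage median exceeded the endothelial median of 0.394 by 0.549 (95% interval over genes 0.224 to 0.830). Cyclic loess left the matrix median at 1.03. It was run on deposited values that were already normalized, so it cannot exclude the authors' normalization. Combination rats under (0.0494 and 0.0756) the GAPDH differences of nevirapine rats (0.197 to 0.211) had medians of both lists together of at least 0.771. Rat73, over them (0.334), had 1.12, against -0.0467 to 0.0475 in nevirapine rats. The rise was thus seen on both sides of that range. These genes had already been found to rise and rat73 alone lay above the range, so RNA quality cannot be excluded. As a hypothesis found in the same data and not tested here, matrix deposition together with macrophages may underlie the rise, and staining these livers for both would test it. A gain or activation of macrophages cannot be separated here, and hepatocyte loss stays open, since rats were not resampled.

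Endothelial, macrophage, T and NK cell and stellate cell lists moved up 3 h after galactosamine, but adjusted p = 0.342 to 0.778 with an estimated correlation. Lists of 5 other cell types were not called. The stellate call by fry was lost without rat1, rat2, rat17 or rat18 and with the mean of probe sets (adjusted p = 0.0615). A lower share of hepatocyte RNA would raise markers of all other cells alike, but the macrophage median of 1.01 exceeded the stellate cell median of 0.303 by 0.703 (0.344 to 0.945). With the GAPDH difference as a covariate the macrophage median was 0.988, which argues against RNA quality as this difference measures it. After cyclic loess it was 0.983, but the values were already normalized, so the authors' normalization cannot be excluded. As a hypothesis not tested here, macrophages may have responded within 3 h, and a lower hepatocyte share stays open.

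Rat63, a combination rat at 3 h, lacked the fall of 606 genes that fell at least 2-fold after galactosamine, with a median of -0.0604 against -0.867 and -1.09 in rat61 and rat62. A swap with a nevirapine rat of 3 h is argued against by the lowest nevirapine rat's -0.158. The GAPDH difference of 0.260 lies above the 0.127 to 0.200 of the 5 other rats given galactosamine. Vehicle rats of 3 h, at 0.1918 to 0.5425, had medians of these 606 genes of -0.0308 to 0.0622. The genes were chosen against these 3 vehicle rats and centred on their mean, which favours medians near 0. RNA quality therefore cannot be excluded for rat63. A missed injection was to be excluded if 46 genes that rise after galactosamine rose in rat63 too, and they did, with a median of 0.867 against 0.862 and 1.27 in rat61 and rat62 and -0.117 to 0.190 in vehicle rats. This reading was changed after the result was seen, because the 46 genes were also up by 0.461 in combination rats at 8 d and no group had 7 d of nevirapine alone, so that the bound was wrong. A missed injection therefore cannot be told apart from a weak response, and no biological explanation was tested. Swaps with other groups were not tested and stay open. On the first and second axes of largest variation over the genes (principal components), rat63 lay at -4.58 and 20.2. The 8 d combination rats lay at -4.07 to -2.51 and 15.1 to 22.8, but rat61 at -19.3 and 37.9 and rat62 at -21.6 and 49.1.

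Splitting 6 rats into 3 and 3 gives 10 splits, too few for a share under 0.05. In each of 20 comparisons the real split alone, 1 of 10, gave as many genes. The real count and the highest other were 4680 and 2 for galactosamine at 3 h, 8357 and 287 at 24 h, and 5 and 0 at 8 d. For nevirapine they were 2142 and 17 at 3 h, 1589 and 20 at 24 h, 2472 and 1 at 48 h, and 1978 and 0 at 15 d. For the combination they were 4627 and 1601 at 3 h, 5219 and 4 at 24 h, 2265 and 204 at 48 h, and 3521 and 1 at 8 d. Against galactosamine the combination had 2518 and 125, 5371 and 1290 at 24 h, and 1594 and 0 at 8 d. Against nevirapine it had 3239 and 2900, 5032 and 14, 2472 and 13, and 1763 and 0. The interaction had 401 and 0, and the vehicle groups 473 and 0. The split with 2900 genes exchanged rat63 and rat31, that with 1601 rat63 and rat3, and that with 1290 rat79 and rat24. No cause of these counts was tested.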

How the results depend on the processing

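The GAPDH covariate and leaving out 3 arrays were chosen afterwards. With the prior with trend, the mean of probe sets and the GAPDH covariate, every count of genes was within 1.5 times that reported, as was the 1 for treated groups compared directly. With each rat left out in turn the counts at 3 h, 24 h, 48 h and 8 d were 3862 to 4304, 7567 to 8156, 3708 to 5322 and 0 to 67 for galactosamine, 3178 to 4878, 4404 to 4962, 1104 to 2380 and 2418 to 3156 for the combination, 1602 to 2631, 4550 to 5043, 2407 to 4567 and 931 to 1671 for the combination against galactosamine, and 1588 to 4388, 4020 to 4845, 1374 to 2528 and 1023 to 1612 for the combination against nevirapine. At 3 h, 24 h, 48 h and 15 d of nevirapine they were 1313 to 1803, 924 to 1364, 1359 to 2094 and 1147 to 1480. The interaction had 107 to 501 genes and the vehicle groups 135 to 235. Where 1 galactosamine rat remained at 48 h, it was assumed to vary like the other groups. No called list or named gene turned its direction without 1 rat, but 56 of 188 called lists and 555 of 1669 called named genes lost their call without some rat. Called named genes that lost and kept their call numbered 303 and 1366 with only the groups compared in the fit, 144 and 781 with all vehicle rats as 1 control, 92 and 496 without 3 arrays, 90 and 1579 with array weights, 75 and 1592 with the mean of probe sets, 62 and 1607 with the covariate, 59 and 1610 after cyclic loess, 40 and 1629 with trend, 34 and 49 against 8 d vehicle, 9 and 46 for treated groups compared directly, and 1 and 1287 without the dimmest genes. Called lists lost 58 calls, the most of any setting but camera, with only the groups compared in the fit. With camera the number of called lists was 1, and in the other settings run on every list it was 168 to 242. Of 31042 probe sets that are not controls, 12075 had a mean under the highest of the bacterial controls, and signal over background limits what can be said of them. Among called genes with further probe sets, up to 181 of 2861 (galactosamine at 24 h) had one that was called the other way. The pooled vehicle control was not run between vehicle groups, where it cannot be defined.

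The cause was not tested for any value that follows. With only the groups compared in the fit, counts were 10 for galactosamine at 8 d, 1279 and 4299 for nevirapine at 3 h and 15 d, 2138 and 374 for the combination at 3 h and 48 h, 757, 2739, 1772 and 3125 for the combination against galactosamine at 3 h, 24 h, 48 h and 8 d, 371 and 533 against nevirapine at 3 h and 48 h, 1340 for the interaction and 1404 for the vehicle groups. Array weights gave 293 for galactosamine at 8 d, 3309, 2499, 4652 and 5018 for nevirapine from 3 h to 15 d, 5557 for the combination at 8 d, 3956 and 3547 against galactosamine and nevirapine, 2076 for the interaction and 2379 for the vehicle groups. With the dimmest 40% of genes left out, the combination against nevirapine at 8 d had 1070 and the interaction 215. Cyclic loess gave 20 for galactosamine at 8 d, and all vehicle rats as 1 control 718, and 1396 for nevirapine at 48 h. The combination had 1763 at 8 d against 8 d vehicle, and 1478 at 48 h without the 3 arrays.

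Directions turned for these lists, with adjusted p in the alternative: with the dimmest genes left out, erythroid genes for nevirapine at 3 h (0.0495) and mast cell genes for the combination at 8 d (0.0856) and at 48 h against galactosamine (0.0207) and nevirapine (0.501). After cyclic loess these were acute phase genes for galactosamine at 24 h (0.0255) and hepatocyte genes for the combination against galactosamine at 24 h (0.616). Against all vehicle rats they were clock genes for galactosamine at 48 h (0.919) and fatty acid oxidation genes for the combination at 48 h (0.0466). Against all vehicle rats log2 changes turned to 0.01 for Per3 with galactosamine at 24 h, 0.06 for Creld2 and 0.23 for Spetex2l1 at 8 d, -0.01 for Nr0b2 and -0.32 for Usp2 with nevirapine at 3 h, -0.14 for Npas2 at 24 h, and -0.13 for Cdkn1a, 0.22 for Srebf1 and 0.50 for Per3 at 48 h. With the combination they turned to 0.00 for Nr1d1 at 3 h, and to -0.27 for Cdkn1a, -0.02 for Eci1, -0.63 for Npas2 and 0.46 for Per3 at 48 h. With the mean of probe sets they were -0.02 for Ptprb with nevirapine at 48 h and 0.10 for Per2 in the interaction.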

Other observations

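No test was run for these values, which were all picked after they were seen.

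Before 8 d, Postn, Lox and Mmp12, picked by hand, differed between combination rats of 1 group. Over the 37 matrix genes the median log2 change against vehicle of the same time was 0.11, 0.95 and 0.40 in rat61, rat62 and rat63 at 3 h, 0.46, -0.21 and 0.21 in rat67, rat69 and rat79 at 24 h, and -0.06, 0.12 and 1.17 in rat70, rat71 and rat72 at 48 h. Postn had a log2 signal of 7.00 in rat62 and 7.27 in rat63 but 3.37 in rat61 at 3 h, 6.48 in rat67 but 2.34 in rat69 and 3.60 in rat79 at 24 h, and 6.71 in rat72 but 2.95 in rat70 and 2.80 in rat71 at 48 h. Vehicle rats lay between 2.31 and 2.97, and nevirapine rats of 15 d between 2.43 and 2.82. Lox was 5.82, 6.36, 5.90 and 5.42 in rat62, rat63, rat67 and rat72, against at most 4.11 in the other combination rats of these times. The macrophage elastase Mmp12 was 6.46 and 7.35 in rat62 and rat63, 5.24 and 5.14 in rat67 and rat79, and 6.15 and 6.40 in rat70 and rat72. It was 4.25 in rat61, 3.90 in rat69 and 4.54 in rat71.

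Galactosamine alone had some of this at 48 h, where Postn was 4.31 and 5.36 and Mmp12 5.53 and 5.32 in the 2 rats. Rat31, taken 3 h after a first dose of nevirapine, had a Postn signal of 4.43 and a Lox signal of 5.61, against 2.47 and 2.48 for Postn in the other rats of its group.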
